A study of Mus musculus with 6 samples.

How the data were processed

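Total RNA of dissected skin from 3 wild type and 3 Hoxc13 targeted mice was hybridised to Affymetrix arrays. Per the labels' protocols, tissue was kept in RNAlater, RNA was isolated on RNeasy columns with DNase treatment and checked on a Bioanalyzer, and biotin-labelled RNA was made by oligo(dT)-primed one-cycle amplification, which reads the 3′ end of transcripts. The authors deposited log2 values summarised by RMA, per the submitters' processing notes, whose version is not given in the sources used here. RMA corrects background, quantile normalises the arrays and summarises the probes of a probe set. It forces the arrays to near-identical distributions, so a change in total RNA cannot be seen, and it compresses differences near background. No detection calls were used here. No counts exist for arrays, and the number of arrays limits the precision.

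The table held 16395 probe sets, of which 64 control probe sets were left out, and 16331 were tested. The array annotation gave 1 gene symbol for 15644 probe sets, several for 0, and did not list 687, which stay unnamed here. Identifiers of the 15644 matched Entrez gene numbers. In the RefSeq gene table of GRCm38.p6, used for names and neighbours only, 15617 were found and 0 had another symbol. Each gene had a single probe set. Samples were grouped by their labels, and replicate numbers were taken from the titles.

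Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a single prior, two-sided), without a filter or a block, and with Benjamini-Hochberg adjustment over the 16331 probe sets at a threshold of 0.05. The prior had 3.53 degrees of freedom and the median standard error was 0.0914. The median difference over all probe sets was 0.0247. A size threshold of 2-fold was a log2 change of 1. Gene lists (31, with 27 genes in more than 1 list) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 31 lists. Of these, 16 passed camera with the preset correlation, 0 with the estimated correlation and 5 passed fry. List means and the type I against type II comparison were tested by exact permutation over 20 arrangements, where the smallest two-sided p is 0.1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

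The tests, the lists and the naming rule were fixed before the data were examined. Named were Hoxc13, the follicle genes Foxn1, Foxq1, Dsg4, Msx2 and Lef1 whatever their values, and the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap. From each list up to 4 called members with the smallest adjusted p were named, or the member with the smallest p where none passed. If fewer than 5 genes had passed in a direction, the 5 with the smallest p would have been named. Genes named beyond this rule are said to be so.

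The test was tried on simulated data with 16331 probe sets, 200 of them changed, in 20 simulations. It recovered 64.7% of changes at a log2 size of 0.5, 98% at 1, 99.8% at 2 and 100% at 4, with 5.51% false among calls and a median of 0 calls where nothing changed. Camera with the preset correlation called 100% of changed lists and 5% of unchanged lists at an unadjusted p under 0.05. Every gene of a changed list was raised by a log2 size of 1, so the 100% does not cover lists with smaller or mixed changes. The 5% rests on 1 list in each of the 20 simulations. The simulated probe sets varied independently and no simulated array stood apart. These rates therefore do not cover lists whose genes move together or a group with an outlying array. In the real lists the estimated correlation reached 0.82 (glycine-tyrosine-rich keratin-associated proteins).

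Alternatives were a filter on probe sets of low mean level, a repeated quantile normalisation, centring of each array, an intensity trend with a robust prior, array weights, the replicate number as a block, no variance moderation, and leaving out each array in turn.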

Results

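Gene expression in dissected mouse skin was measured on Affymetrix arrays in 3 wild type samples and 3 samples carrying a targeted allele of Hoxc13, a homeobox transcription factor of the hair follicle. All 6 samples were labelled as skin on a C57BL/6 background, with 5 dpn in their titles and male as the sex. The design text calls the 3 samples of each group independent. The comparison between the groups asks which skin transcripts differ when Hoxc13 is altered. Each array gave log2 values for 16331 probe sets after control probe sets were set aside, with a median of 7.405 on every array. Of these, 15644 probe sets had a gene name. With 3 arrays per group, the number of arrays limits the precision, and p-values measure the spread between these samples.

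The Hoxc13 probe set (Entrez gene 15422) read 9.75 ± 0.11 in wild type skin and 9.15 ± 0.52 in mutant skin (SD, n = 3 each). The mutant values were 8.95, 8.75 and 9.74 in replicates 1, 2 and 3. The difference of -0.61 (SE 0.23) did not pass the limma test (adjusted p = 0.293). Without mutant replicate 3 it was -0.90 (adjusted p = 0.00114). Whether the probes lie inside the disrupted part of the gene is not given in the sources used here, so this level does not check the labels.

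The groups were separated along the first principal component, which held 73.5% of the variance. Mutant replicate 3 stood apart from the other mutant arrays along the second (15.5%), at -26.6 against 13.1 and 11.1. Across probe sets, its correlation with mutant replicates 1 and 2 was 0.989 and 0.990, against 0.997 between those arrays and 0.996 to 0.997 among the wild type arrays. Probe sets are not independent replicates. On every array, Xist, the transcript of the inactive X chromosome, read between 11.15 and 11.67. The 6 probe sets of Y-linked genes read between 2.98 and 4.89, although the labels give the animals as male. The top of this range came from Usp9y (4.40 to 4.89). The other Y-linked probe sets read at most 4.185, so values above that level are matched by Usp9y alone.

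Hair keratins and keratin-associated proteins, the filament and matrix proteins of the shaft, made up most of the large decreases in mutant skin. Of the 46 genes whose values were over 16-fold lower, 38 belonged to these families. Krtap16-3 read 12.93 ± 0.29 in wild type and 5.01 ± 0.95 in mutant skin (SD, n = 3 each), a difference of -7.91. Mutant values of many of these genes lay near the lower quartile of the arrays (5.485 on wild type replicate 1), where no detection calls separate signal from background. The sizes of these decreases are therefore differences of RMA values, and their order is not a ranking of the true changes. Increases were smaller, the largest of a named gene being that of Myh2 (1.23, SE 0.19, adjusted p = 0.0195). The limma test called 339 of 16331 probe sets, 78 higher and 261 lower in mutant skin. Among these, 134 changed at least 2-fold, 4 higher and 130 lower. They comprised 321 named genes, 75 higher and 246 lower, and 18 probe sets without a name here. The values of the groups did not overlap in all 339 of these and in 20.3% of all probe sets, where chance gives 10%. The count changed with the arrays used, and most without mutant replicate 3. Without mutant replicate 3 it was 2316 (1298 higher, 1018 lower), and all 339 probe sets were among them. Without wild type replicates 1, 2 or 3 it was 157, 166 or 151, and without mutant replicates 1 or 2 it was 158 or 176. These counts lie close together, and each of these fits has fewer arrays and keeps mutant replicate 3. A call lost in such a fit, here and throughout, may reflect lower power. It does not by itself show that 1 array carried the effect. The fit without mutant replicate 3 drops the mutant array that stood apart. It keeps mutant replicates 1 and 2, which correlate at 0.997. Its adjusted p-values and counts, here and throughout, may therefore understate the spread between mutant animals.

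**Figure D1:**
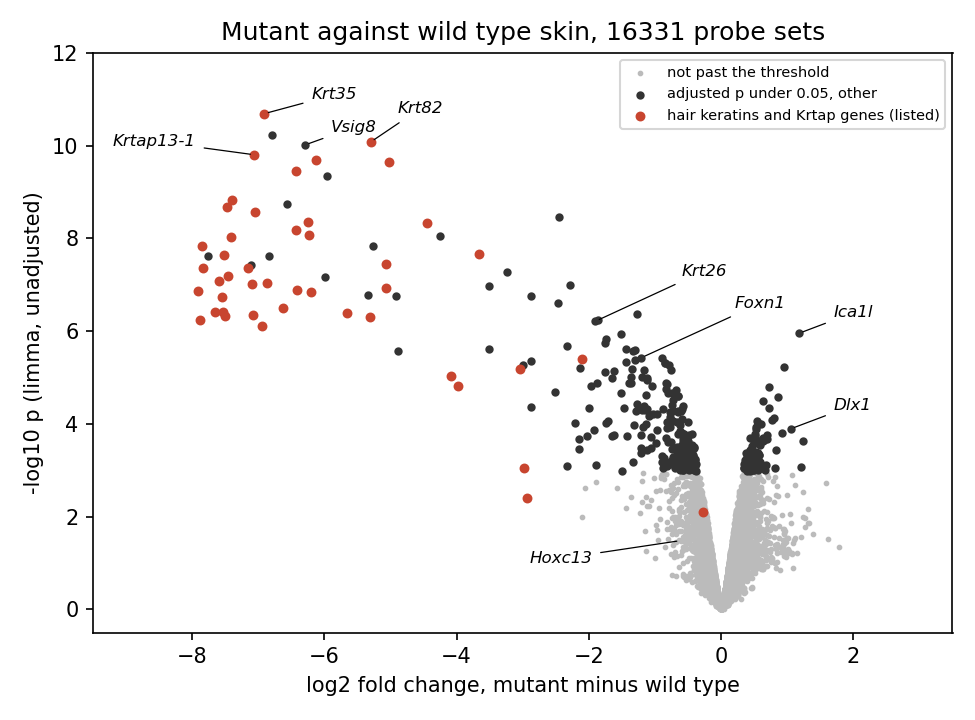
Each point is a probe set, with the log2 fold change (mutant minus wild type) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; dark points pass an adjusted p of 0.05 and red points are the listed hair keratin and keratin-associated protein genes. The lower genes reach a log2 change of -7.91 and the higher named genes 1.23.

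All 7 measured type I hair keratins fell, with a median log2 change of -6.43. Krt35 went from 13.14 ± 0.09 to 6.22 ± 0.21 (SD, n = 3 each), a change of -6.91 (SE 0.11, adjusted p = 3.32e-07). Krt34, Krt31 and Krt33b changed by -7.40, -6.43 and -6.13, and Krt33a by -7.65 (SE 0.47). All 3 measured type II hair keratins fell as well, with Krt86 at -7.05, Krt82 at -5.30 and Krt84 at -2.11. The counts were the same adjusted over the list alone, 7 and 3. Camera with a preset correlation gave adjusted p = 9.7e-30 for the type I and 1.73e-12 for the type II list. With an estimated correlation the adjusted p was 0.0647 for both.

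Matrix protein genes fell together with the keratins. Of 24 measured sulfur-rich keratin-associated protein genes, 22 fell and 24 did so adjusted over the list alone, with a median of -6.21. Krtap13-1 changed by -7.06 (SE 0.15, adjusted p = 5.12e-07), Krtap14 by -7.47, Krtap3-3 by -6.25 and Krtap26-1 by -5.02. Krtap9-3 changed by -7.51. All 11 glycine-tyrosine-rich members fell, also adjusted over the list alone (11), with a median of -7.54. Krtap7-1 changed by -7.85 (SE 0.31, adjusted p = 1.1e-05), Krtap19-2 by -7.88, Krtap19-1 by -7.84, Krtap6-5 by -7.60, Krtap19-3 by -7.55, Krtap6-1 by -7.54 and Krtap19-4 by -6.44. Krtap16-3 (-7.91) was counted with the sulfur-rich list by its family number, and its protein class was not checked. The gene model Gm10228, which is in no list, changed by -7.76. In mutant replicate 3 all 11 glycine-tyrosine-rich members lay below the mean of mutant replicates 1 and 2, with a median difference of -1.46. Camera gave adjusted p = 4.34e-63 and 5.53e-35 for the sulfur-rich and glycine-tyrosine-rich lists. With an estimated correlation these were adjusted p = 0.0647 and 0.0945. Members of these families are close in sequence, so the value of a single gene is uncertain.

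The list means of type I and type II hair keratins changed by -6.09 and -4.82, a difference of -1.27 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays allow). They started from 12.13 and 10.07 in wild type skin and read 6.04 and 5.25 in mutant skin, low levels at which background was not separated from signal. Without probe sets of low mean level the difference was -0.32. These values do not show that the families fell by different amounts.

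Other genes of the hair shaft followed in part. Of 26 measured members, 13 fell and none rose, and adjusted over the list alone 16 fell and 2 rose, with a median of -0.97. Vsig8 changed by -6.29 (SE 0.13, adjusted p = 3.93e-07), Psors1c2 by -5.96, the orphan receptor gene Gprc5d by -5.26 and Lyg2 by -4.25. Camera gave adjusted p = 1.06e-23, and adjusted p = 0.127 with an estimated correlation. Without mutant replicate 3, 22 members were lower and 1 higher. Fry, which tests whether a list's genes move one way on balance, passed for these 5 hair shaft lists and for no other of the 31.

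**Figure D2:**
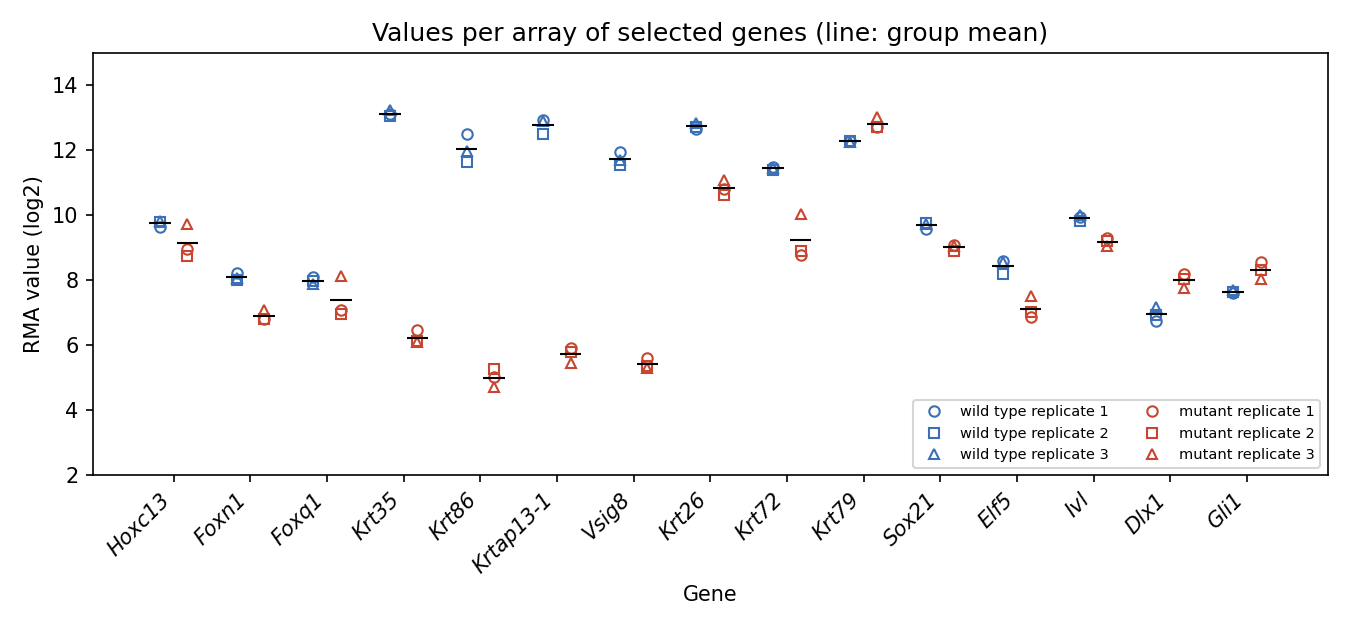
RMA values (log2, vertical axis) of 15 genes on each array, wild type in blue and mutant in red, with a symbol per replicate number and a line at each group mean of 3 arrays. Krt35, Krt86, Krtap13-1 and Vsig8 change by -6.91, -7.05, -7.06 and -6.29, and the Hoxc13 and Foxq1 values of mutant replicate 3 lie near the wild type values.

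Inner root sheath and companion layer genes, which encode the sheath around the growing shaft, mostly did not pass the test. Of 14 measured members, Krt72 fell by 2.20 (SE 0.30, adjusted p = 0.0106) and Krt26 by 1.90 (SE 0.12, adjusted p = 1.72e-04). Krt79 rose by 0.54 (SE 0.10, adjusted p = 0.0435), but it is also on the sebaceous gland list and is not particular to the sheath. The other 11 did not pass. The Krt79 call was lost when any single array other than mutant replicate 3 was left out (range 0.43 to 0.60), and that of Krt72 when any single wild type array or mutant replicate 2 was left out (-2.60 to -1.98). Adjusted over the list alone, 3 fell and 1 rose. The median was -0.104 and the mean -0.39. Camera gave adjusted p = 0.0218, and adjusted p = 0.734 with an estimated correlation. All 14 members were higher in mutant replicate 3 than in the mean of mutant replicates 1 and 2, by a median of 0.39. Its list mean of 12.11 lay within the wild type range of 12.09 to 12.18 (exact permutation p = 0.2, two-sided). Without that array 7 members were lower and 1 higher, with a median of -0.28, and without wild type replicate 1 the median was -0.16. The camera call was lost without wild type replicate 2 (median -0.0371), mutant replicate 1 (0.013) or mutant replicate 2 (-0.0323).

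Among 43 measured follicle regulators 4 fell and 1 rose. Foxn1 (Entrez gene 15218), the transcription factor mutated in nude mice, went from 8.10 ± 0.11 to 6.89 ± 0.16 (SD, n = 3 each), a change of -1.21 (SE 0.10, adjusted p = 8.78e-04). Elf5, an ETS family factor, fell by 1.32, the signalling gene Bmp2 by 0.88 and the HMG box factor Sox21 by 0.66. Dlx1, a distal-less homeobox factor, rose by 1.05 (SE 0.15, adjusted p = 0.013). The call was lost for Dlx1 without wild type replicates 1 or 2 or mutant replicates 1 or 2 (range 0.95 to 1.18). It was lost for Elf5 without wild type replicates 1 or 3 or mutant replicate 2 (-1.51 to -1.20), and for Sox21 without wild type replicates 2 or 3 (-0.72 to -0.60). Adjusted over the list alone, 4 fell and 3 rose, and without mutant replicate 3, 11 fell and 7 rose. The median of the list was 0.0723, its mean -0.0278 and the camera direction lower, with adjusted p = 0.90. Foxq1 was at -0.60 (SE 0.28, adjusted p = 0.388), Msx2 at -0.36 (adjusted p = 0.208) and Lef1 at -0.45 (adjusted p = 0.35), none past the threshold. Without mutant replicate 3 these genes were at -0.97, -0.47 and -0.66 with adjusted p = 6.05e-04, 0.0145 and 0.0177. The array left out in that fit had the highest mutant value of each of these genes. Dsg4 had no probe set named here.

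Signalling pathways showed few called genes with all 6 arrays. In the Hedgehog list (15 measured) the target gene Gli1 rose by 0.66 (SE 0.13, adjusted p = 0.0488) and Ccnd2 by 0.35, while Gli3 fell by 0.42. Adjusted over the list alone 7 rose and 1 fell, as many as without mutant replicate 3. The median was 0.19, with camera adjusted p = 0.00608, and adjusted p = 0.588 with an estimated correlation. Exact permutation of the list mean gave p = 0.1 (two-sided), the smallest possible. Its mean in mutant replicate 3 (7.71) lay above the wild type range of 7.53 to 7.59. Without wild type replicate 2 the median was 0.30, and without probe sets of low mean level 0.39. In the BMP list (23 measured) Bmp8a fell by 1.13 (SE 0.12, adjusted p = 0.00359) and Bmp2 by 0.88, and adjusted over the list alone 3 fell and 1 rose. Its median was -0.0783, with camera adjusted p = 0.0218, and adjusted p = 0.604 with an estimated correlation. Exact permutation of its list mean gave p = 0.1 (two-sided), with mutant replicate 3 (8.711) just below the lowest wild type value (8.712). Of the 37 measured genes on the Wnt list only Wnt3 passed (-0.48), also adjusted over the list alone (1 gene), and the list median was 0.072. Wnt3 read 4.83 and 4.35 in wild type and mutant skin, within the range of the Y-linked probe sets, so neither group is shown to be above background. Wnt3a, which is not on the list and was looked at after its values were seen, was also called lower (-0.56, adjusted p = 0.0158). None of 32 other Hox genes passed, with the smallest p at Hoxd9 (0.49, adjusted p = 0.0741) and 2 higher adjusted over the list alone. None of 22 Notch pathway genes passed, with the smallest p at Heyl (-0.34, adjusted p = 0.091), and 0 adjusted over the list alone. Camera did not call these 3 lists (adjusted p = 0.606, 0.435 and 0.982). Without mutant replicate 3, 5 Wnt genes were higher and 5 lower, 3 Hox genes higher and 1 lower, 1 Notch gene higher and 3 lower, and 1 BMP gene higher and 6 lower. When any single array other than mutant replicate 3 was left out, the calls of Gli1 (range 0.54 to 0.80), Ccnd2 (0.33 to 0.37), Gli3 (-0.44 to -0.39) and Bmp2 (-0.98 to -0.69) were lost. That of Wnt3 was lost without wild type replicates 1 or 2 or mutant replicates 1 or 2 (-0.53 to -0.45). The camera call of the BMP list was lost without wild type replicate 2 (median -0.0812) or mutant replicate 2 (-0.0225), and its median was -0.0432 without mutant replicate 1 and -0.14 without mutant replicate 3.

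**Figure D3:**
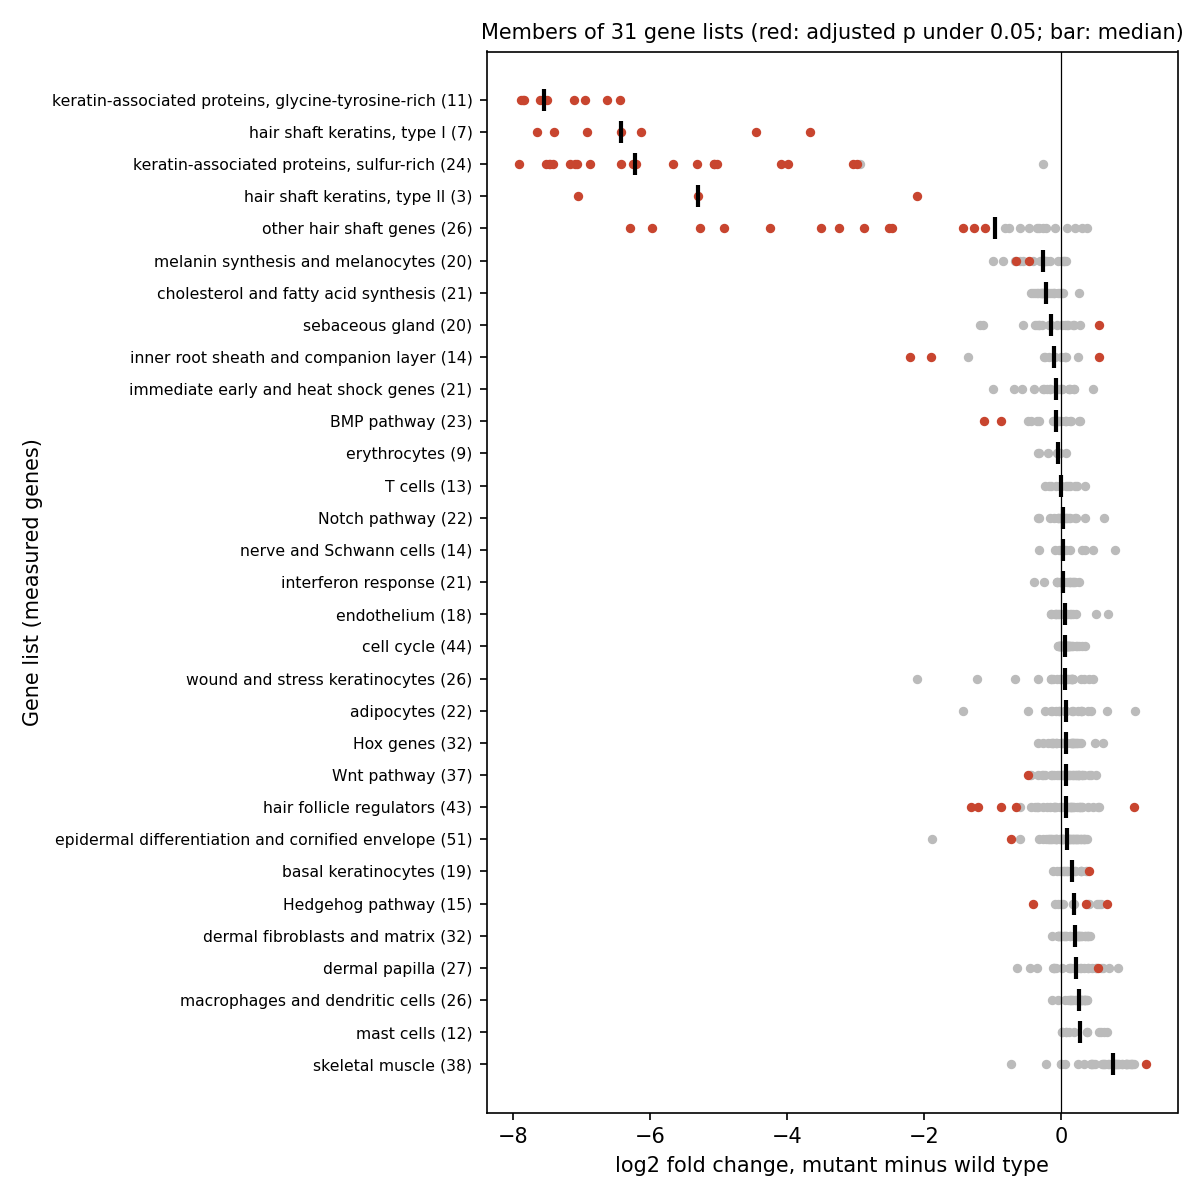
Log2 fold changes (mutant minus wild type, horizontal axis) of the members of 31 gene lists, with the number of measured genes in brackets; red points pass an adjusted p of 0.05 and the bar is the list median. The 4 hair keratin and keratin-associated protein lists have medians from -7.54 to -5.30, and all other medians lie between -0.97 and 0.75.

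The pigment cell list had a lower median in mutant skin, but its mean in mutant replicate 3 lay within the wild type range. Of 20 measured melanin synthesis and melanocyte genes, the melanosomal receptor gene Gpr143 fell by 0.67 (SE 0.11, adjusted p = 0.0247) and the melanocortin receptor gene Mc1r by 0.47 (adjusted p = 0.0435). The other 18 did not pass, and 8 fell adjusted over the list alone. The median was -0.26, with camera adjusted p = 1.09e-07, and adjusted p = 0.588 with an estimated correlation. All 20 members were higher in mutant replicate 3 than in the mean of the other mutant arrays, by a median of 0.41. Its list mean was 8.95, against 8.93 to 9.04 in wild type and 8.53 and 8.46 in the other mutant arrays (exact permutation p = 0.2, two-sided). Without it 13 members were lower and the median was -0.42. The calls of Gpr143 (range -0.72 to -0.57) and Mc1r (-0.52 to -0.41) were lost when any other single array was left out.

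Few genes of the epidermis between follicles passed with all 6 arrays. Of 51 measured differentiation and cornified envelope genes only Ivl (involucrin) passed, falling by 0.74 (SE 0.09, adjusted p = 0.00559). Adjusted over the list alone 2 fell and 1 rose, and without mutant replicate 3, 10 fell and 10 rose. Camera did not call the list (median 0.0843, adjusted p = 0.606). Among 19 basal keratinocyte genes the laminin gene Lamb3 rose by 0.40 (adjusted p = 0.0494), and 4 rose adjusted over the list alone. The Lamb3 call was lost when any single array other than mutant replicate 3 was left out (range 0.37 to 0.44). The list median was 0.15, with camera adjusted p = 0.0112, and adjusted p = 0.604 with an estimated correlation. Exact permutation of the list mean gave p = 0.2 (two-sided). Without mutant replicate 3 the camera call was lost, 4 members were higher and the median was 0.0395. None of 26 wound and stress genes passed, nor adjusted over the list alone (0), with S100a8 at -1.23 (adjusted p = 0.158). That list had a median of 0.0582, a mean of -0.084 and camera adjusted p = 0.693, and without mutant replicate 3, 1 member was higher and 3 lower. Krt79 was the only gene called of 20 sebaceous gland genes, with 2 lower and 1 higher adjusted over the list alone. The sebaceous list had a median of -0.16 and camera adjusted p = 0.162, and without mutant replicate 3, 8 members were lower and 1 higher. None of 21 cholesterol and fatty acid synthesis genes passed, nor adjusted over the list alone (0), with Tm7sf2 at -0.30 (adjusted p = 0.114). Their median was -0.23, with camera adjusted p = 2.61e-05, and adjusted p = 0.604 with an estimated correlation. Exact permutation of their list mean gave p = 0.1 (two-sided), with mutant replicate 3 (9.647) just below the lowest wild type value (9.650). The median was -0.114 without mutant replicate 1, and without mutant replicate 3, 7 members were lower and 1 higher.

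Muscle and stromal lists had higher medians in mutant skin, with few single genes called, and in mutant replicate 3 none of their means lay above the wild type range. Of 38 skeletal muscle genes, the fast myosin heavy chain gene Myh2 rose and the other 37 did not pass, with a median of 0.75 and 1 gene higher adjusted over the list alone. The Myh2 call was lost without wild type replicate 1 or mutant replicates 1 or 2 (range 0.99 to 1.37). The list mean differed between groups by 0.64, less than its range of 0.94 over the wild type arrays (exact permutation p = 0.2, two-sided). Camera gave adjusted p = 1.2e-07, and adjusted p = 0.604 with an estimated correlation. In mutant replicate 3 all 38 were lower than in the mean of the other mutant arrays, with a median difference of -0.80, and without it 19 rose. The list mean there was 9.29, against 8.75 to 9.69 in wild type. The median was 0.46 without mutant replicate 1 and 0.47 without wild type replicate 3. Of 27 dermal papilla genes the activin subunit gene Inhba rose by 0.53 (SE 0.09, adjusted p = 0.0301), and adjusted over the list alone 8 rose and 3 fell. The median was 0.21, with camera adjusted p = 0.0103, and adjusted p = 0.604 with an estimated correlation. None of 32 dermal fibroblast and matrix genes passed, with Thy1 at 0.34 (adjusted p = 0.0598), and 6 rose adjusted over the list alone. Their median was 0.19, with camera adjusted p = 0.00241, and adjusted p = 0.604 with an estimated correlation. Mutant replicate 3 lay lower in both lists, by medians of -0.37 and -0.23, and without it 15 rose and 3 fell in the first list (median 0.34) and 14 rose in the second. Its list means were 7.66 for dermal papilla genes (7.66 to 7.71 in wild type, exact permutation p = 0.3) and 10.88 for fibroblast genes (10.85 to 10.93, p = 0.2). The Inhba call was lost when any single array other than mutant replicate 3 was left out (range 0.48 to 0.61). The camera call was lost for dermal papilla genes without mutant replicate 1 (median 0.18) and for fibroblast genes without mutant replicate 2 (0.0974).

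Markers of immune and other cells held no called gene with all 6 arrays. The median of 26 macrophage and dendritic cell genes was 0.26 (camera adjusted p = 1.98e-04, and adjusted p = 0.588 with an estimated correlation), with Fcer1g at 0.35 (adjusted p = 0.16). The median of 12 mast cell genes was 0.27 (camera adjusted p = 0.00542, and adjusted p = 0.588 with an estimated correlation), with the histidine decarboxylase gene Hdc at 0.62 (adjusted p = 0.0927). Adjusted over the list alone, 0 and 1 of these genes rose. Exact permutation of the list means gave p = 0.1 (two-sided) for both lists, the smallest possible. Mutant replicate 3 lay above the wild type range in both, at 8.10 against 7.86 to 7.92 and at 7.11 against 6.96 to 7.07. Without mutant replicate 2 the medians were 0.17 for macrophage and 0.17 for mast cell genes, and without mutant replicate 3, 9 macrophage genes were higher and 1 lower and 5 mast cell genes were higher. Without probe sets of low mean level the mast cell list lost its camera call (median 0.55). Camera called none of the remaining lists (adjusted p from 0.115 to 0.933). Cell cycle genes (44 measured) had a median of 0.0582 with Mcm7 at 0.34, and adipocyte genes (22) had 0.0642 with Lep at -1.44. Endothelial genes (18) had 0.046 with Vwf at 0.50, and nerve and Schwann cell genes (14) had 0.0235 with Pmp22 at 0.46. The 13 T cell genes had a median of -0.006 and a mean of 0.0274, with Thy1 again the smallest p. The 9 erythrocyte genes had -0.053 with Alas2 at -0.35, and 21 immediate early and heat shock genes had -0.0793 with Egr1 at 0.46. The 21 interferon response genes had 0.0277 with Oasl1 at -0.25. Adjusted over the list alone, 3 nerve genes and 1 T cell gene rose, and 0 genes of the other 6 lists passed. With mutant replicate 3 left out, 5 cell cycle, 3 adipocyte, 2 endothelial and 2 interferon response genes were higher, and 6 immediate early and heat shock genes and 2 erythrocyte genes lower. Nerve genes then had 2 higher and 1 lower, and T cell genes 1 each way.

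**Figure D4:**
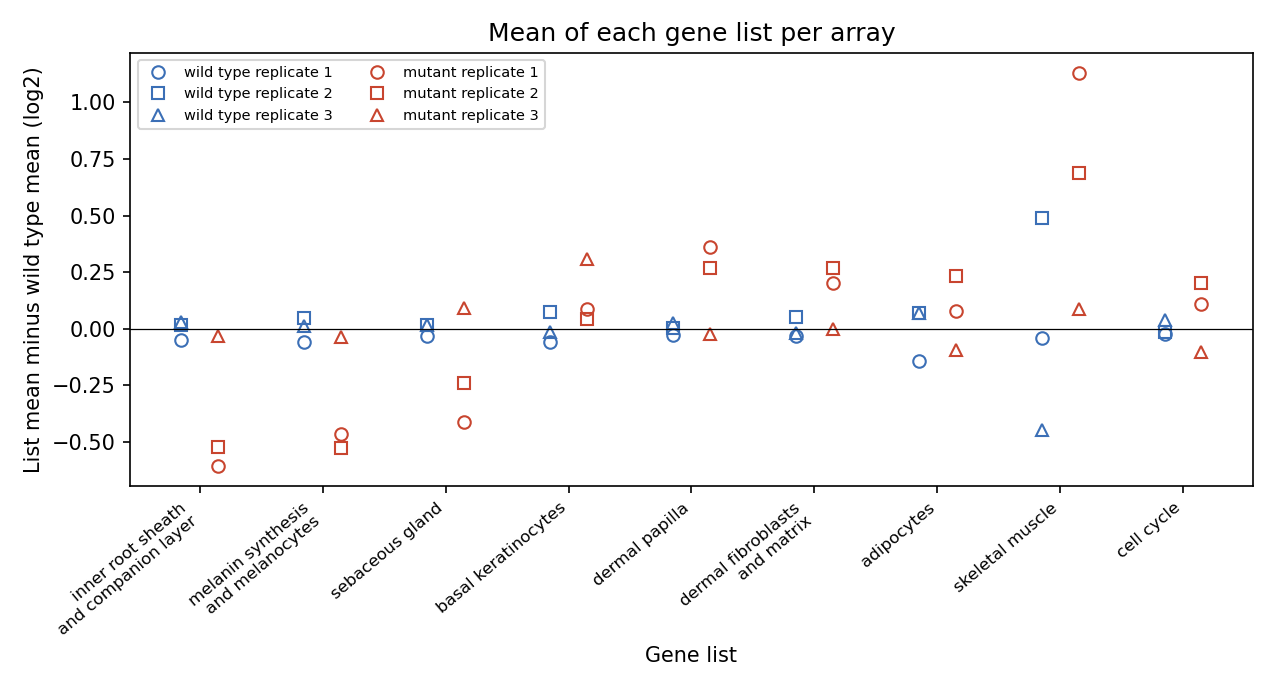
Mean log2 value of 9 gene lists on each array minus the wild type mean (vertical axis), wild type in blue and mutant in red, with a symbol per replicate number. Mutant replicate 3 lies apart from the other mutant arrays in the inner root sheath and melanocyte lists (median member 0.39 and 0.41 higher) and the skeletal muscle list (-0.80).

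The genes with the largest increases outside the lists had varied functions. Ica1l rose by 1.18 (SE 0.08, adjusted p = 3.03e-04), from 5.43 ± 0.13 to 6.61 ± 0.04 (SD, n = 3 each). The G protein signalling regulator gene Rgs2 rose by 0.95, the sialyltransferase gene St6galnac5 by 0.93, and Irak3, a negative regulator of Toll-like receptor signalling, by 0.86. The neurotensin gene Nts, low in both groups (4.87 and 5.70), rose by 0.83. The wild type means of Ica1l (5.43) and St6galnac5 (5.34) lay below the lower quartile of wild type replicate 1 (5.485). That of Nts lay within the range of the Y-linked probe sets. Background was not separated from signal at these levels, so the sizes of the increases of Ica1l, St6galnac5 and Nts are uncertain. The muscle genes Lmod2 and Ankrd2 rose by 0.81 and 0.80 and the serotonin transporter gene Slc6a4 by 0.77. The calls of Nts (range 0.75 to 0.96), St6galnac5 (0.78 to 1.02), Lmod2 (0.64 to 0.96) and Slc6a4 (0.69 to 0.87) were lost when any single wild type array was left out. Those of Nts, Lmod2 and Slc6a4 were also lost without mutant replicate 1 and that of Nts without mutant replicate 2. Called higher genes had a median change of 0.53, against 1.05 in size for called lower genes.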

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

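All alternatives were chosen before the data were examined. Repeated quantile normalisation and an intensity trend with a robust prior moved no count by over 1.5 times (342 and 337 probe sets). The repeated normalisation could change little, since RMA had already quantile normalised the arrays. Centring on array medians could change nothing, since all arrays had the same median. Some settings could not be applied: no probe set carried a shared-probe suffix and each gene had a single probe set, so leaving such probe sets out, averaging probe sets and choosing the most variable one gave no value. The filter on low levels left 8166 probe sets and called 286, of which 237 were among the 339. It took the call from mast cells (median 0.547, fewer genes tested), moved the Hedgehog median to 0.39 and moved type I against type II hair keratins to -0.32, with fewer keratins measured. Medians of uncalled lists moved too, such as T cell genes from -0.006 to 0.29 and nerve genes from 0.0235 to 0.29, and no list gained a call. Array weights gave mutant replicate 3 a weight of 0.234 against 1.23 to 1.44 elsewhere, and called 1880 probe sets (1041 higher, 839 lower, 228 at least 2-fold) and 1811 genes, with Hoxc13 at -0.83 past the threshold. All 339 were among them. Without variance moderation 84 were called (18 higher, 66 lower, 53 at least 2-fold, 79 genes). With the replicate number as a block 197 were called (22 higher, 187 genes), 182 of them among the 339. Same-numbered arrays had deviations correlating at 0.036, -0.119 and -0.0873, against -0.121 to 0.237 for differently numbered arrays. No pairing by number is visible, though these values, centred within groups of 3 arrays, cannot exclude one. The causes of these shifts were not tested.

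Leaving out each array in turn gave 151 to 2316 probe sets (9 to 1298 higher, 134 to 1018 lower), 110 to 255 at least 2-fold and 143 to 2226 genes. Hoxc13 ranged from -0.90 to -0.41. Camera calls ranged from 14 to 20 lists. List medians that crossed the threshold in some fit ranged from -0.28 to 0.013 (inner root sheath, where the sign turned without mutant replicate 1), -0.144 to -0.0225 (BMP), 0.18 to 0.34 (dermal papilla), 0.0974 to 0.27 (fibroblasts), 0.0395 to 0.22 (basal keratinocytes), -0.0241 to 0.15 (Hox), -0.20 to -0.0398 (sebaceous), 0.0194 to 0.14 (adipocytes), -0.0148 to 0.15 (cell cycle), -0.0888 to -0.0453 (erythrocytes) and -0.29 to 0.0262 (immediate early). Called lists that kept their call had wide ranges too, with 0.46 to 1.01 (muscle), -0.30 to -0.114 (cholesterol), 0.16 to 0.30 (Hedgehog), -0.42 to -0.21 (melanocytes), 0.17 to 0.32 (macrophages) and 0.17 to 0.30 (mast cells). Some lists called in none of these fits had medians that changed sign, such as wound and stress genes (-0.0818 to 0.0972) and endothelial genes (-0.0213 to 0.0975). No called named gene changed direction in any of these settings, and 15 to 18 of them missed the threshold when an array other than mutant replicate 3 was left out, 29 without moderation and 13 with the block.

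With an estimated correlation 0 lists passed. The hair keratin and keratin-associated protein lists also missed this camera test, at adjusted p = 0.0647 to 0.0945, despite medians of -7.54 to -5.30. Missing it here therefore does not show that a list is unchanged. The 16 lists called with the preset correlation had medians of -6.43, -5.30, -6.21, -7.54 and -0.97 (hair shaft), -0.104 (inner root sheath), -0.0783 (BMP), 0.19 (Hedgehog), -0.26 (melanocytes), 0.15 (basal keratinocytes), -0.23 (cholesterol), 0.75 (muscle), 0.19 (fibroblasts), 0.21 (dermal papilla), 0.26 (macrophages) and 0.27 (mast cells). With fry the 5 hair shaft lists passed and the other 11 did not.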

Other observations

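Several further genes passed the limma test, all picked out after their values were seen. Lower in mutant skin were Calhm4 (-6.79), Procr (-3.51), Chac1 (-3.00) and Acsm3 (-2.88). Calhm4 read 4.50 in mutant skin, within the range of the Y-linked probe sets, so the size of its fall is uncertain. Also called lower were the tubulin genes Tubb3 (-1.31), Tubb6 (-0.81) and Tubb2a (-0.63), the claudin genes Cldn7 (-0.86), Cldn8 (-0.79) and Cldn12 (-0.61), and Kitl (-0.65), the ligand of the Kit receptor. Called higher were Fgfr1 (0.53), Igf1r (0.49), Fgfr2 (0.39) and Tgfb1 (0.45). These are single genes, and their families were not tested.

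The tests on replicate 3, muscle, sex and the splits were chosen after the results were seen; those on type II keratins and ATF4 targets were written before their results. The real split gave 339 probe sets, 134 at least 2-fold and 321 genes, and was the only 1 of the 10 splits of the 6 arrays with counts as large, the highest of the others being 0. With 10 splits the share cannot fall under 0.05. Every other split mixes wild type and mutant arrays in a group, which widens the spread within groups. The 0 calls there therefore do not measure what arrays without a group difference would give.

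Mutant replicate 3 differed from mutant replicates 1 and 2 in many lists. Wild type tissue or RNA in it, or a wild type sample under its label, would raise the hair shaft keratin and matrix genes there. Their median was -0.32 relative to the other mutant arrays, and 32 of 45 genes were lower, which argues against such a mixture or swap. The bootstrap interval of -0.784 to -0.203 resampled genes, which move together, on a single array. It does not measure the spread between animals. By list, all 11 glycine-tyrosine-rich members were lower (median -1.46), the 24 sulfur-rich members were split at 12 and 12 (-0.064), and 21 of 26 other hair shaft genes were higher (0.42). Lower RNA integrity is argued against by the control transcripts, since 0 of 4 had their highest 3′ to 5′ difference there. A smaller share of tissue below the epidermis may be involved, as 5 of 6 deeper tissue lists had a lower median member (the nerve list was 0.0485 higher), but the test did not decide it, and a difference between the animals stays open and untested.

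The arrays did not look male. On 6 of 6 arrays Xist lay above the 90th percentile of probe sets (96.4 to 98.0) and all Y-linked probe sets below the 25th, which is what female skin would give. High Xist, the transcript of the inactive X chromosome, argues against the male label for the RNA on all 6 arrays. The count of 6 restates the observation that raised the question and adds no further support. How the label came about was not tested. With 1 or a few mislabelled arrays the others would lack high Xist, and all 6 had it. No biological explanation was tested.

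The skeletal muscle list had a median of 0.75, but 1 of 38 genes passed, and the list's call was lost with an estimated correlation (adjusted p = 0.604) and with fry (adjusted p = 0.317). The median was 0.46 without mutant replicate 1 and 0.47 without wild type replicate 3. A varying amount of muscle in the dissected skin could produce this, since their list mean also ranged by 0.94 over the wild type arrays, where the genotype is constant, against a group difference of 0.64. In wild type skin 34 of 38 genes were highest in replicate 2 and 32 lowest in replicate 3. A range over single arrays is wider than the error of a difference between group means. The comparison therefore cannot exclude an effect of the genotype on muscle, which stays open.

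The following are hypotheses. Type II hair keratin genes lie on the chromosome of Hoxc13, so linked strain sequence or a change of neighbouring genes might have lowered them. Type I keratins, on another chromosome, changed by -6.09, which argues against linked sequence as the only cause of the fall of hair keratins. An added effect of it on type II genes was not tested. Of the 50 nearest non-keratin neighbours of Hoxc13, 0 passed the threshold against 1.77% of other genes (one-sided Fisher's exact p = 1). That argues against a change past the threshold in many neighbours. At such a share few of 50 would pass anyway, so the test cannot exclude a change of some neighbours. The subunit genes of eIF2B, the exchange factor of translation initiation, were noticed after their values were seen and were lower, with Eif2b4 at -0.76, Eif2b3 at -0.73, Eif2b5 at -0.68 and Eif2b1 at -0.39 past the threshold and Eif2b2 at -0.44 not. Of the ATF4 targets seen before, Chac1 (-3.00) and Cth (-0.98) were called lower and Ddit3 (0.39) higher. A change of ATF4 target genes as a group was tested on the 30 other targets, and camera gave p = 5.04e-05 with a preset and 0.134 with an estimated correlation (median -0.138), which leaves it open.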
